A study of Mus musculus with 2 samples.

How the data were processed

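RNA from the mouse line G1E-ER-GATA-1 was compared on 2 two-colour Agilent arrays. G1E is an erythroid line that lacks GATA-1, the main transcription factor of red cell maturation. G1E-ER-GATA-1 carries GATA-1 fused to an oestrogen receptor domain, so that β-estradiol switches it on. Per the labels, cells were transfected with control siRNA or with siRNA against ETO2, the corepressor encoded by Cbfa2t3, and then kept in β-estradiol for 24 h. On both arrays the control RNA carried Cy5 (red) and the ETO2 siRNA RNA carried Cy3 (green), with 1.2 µg of total RNA per dye, per the labels. Dyes were not swapped. Every log2 ratio is given as ETO2 siRNA over control siRNA, the sign of the deposited ratio turned.

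Spot brightness was read by Agilent Feature Extraction 9.1.3.1 with local background, per the file headers, and the deposited spot and background intensity values are linear and not normalized. The deposited processed intensity had been background-subtracted and dye-normalized within each array by the scanner software, per the file headers. The deposited log10 ratio of red over green came from those processed signals. The authors' deposited ratio table held the same log10 values rounded to 3 digits on all 45018 features of each array, with a median of 0 in each column, so that its scale and direction are known and no further centring was seen. Flags for saturation, for signal well above background and for outliers came from the same software, per the file headers. The steps behind the array's probe design and the genome build are not given in the sources used here.

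Mean spot signals were corrected with local median background by normexp with an offset of 50 in limma 3.58.1 (R 4.3.3), and each array was normalized by loess. Of the 45018 features, 1639 were control features, which entered normexp but had weight 0 in loess and were left out of the tests. Outlier flags removed 10 spots on array 1 and 4 on array 2. Spots of a probe were averaged, which concerned 245 probes with 10 spots each. Of 41174 probes, 24426 (59.3%) were well above background on both arrays in at least 1 channel and were kept. A gene was represented by its brightest kept probe. Probe names were updated with the RefSeq gene table of GRCm38.p6: 24375 probes matched by accession, 6301 by symbol and 2426 by synonym, and 8072 kept the name in the array file. This gave 16581 genes and transcripts, of which 12668 had a gene symbol. No coordinates are given, and the table's gene order served only to find neighbouring genes.

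Log2 ratios were tested against 0 with limma's lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 2 arrays leave 1 residual degree of freedom per gene, and eBayes added 13.6 prior degrees of freedom with a prior SD of 0.0905. A sign permutation of 2 arrays cannot give a two-sided p below 0.5, so all adjusted p-values rest on the shared variance model. Labels number the arrays as replicates but do not say that they came from separate cultures, and p-values then measure only the spread between these arrays. Both arrays lay on 1 slide and were scanned on 1 day, so there was no batch to compare. Because the dyes were not swapped, a dye effect specific to a probe has the same sign on both arrays and enters the ratio.

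Gene lists (23) were fixed before the data were examined and tested with camera at a preset correlation of 0.01, with fry beside it, adjusted over the lists. They covered globins, haem synthesis, erythroid membrane proteins, erythroid transcription factors, the ETO family with its corepressor partners, progenitor genes, markers of other blood and tissue cell types, cell cycle, apoptosis, autophagy, stress, interferon response, iron, cholesterol synthesis, glycolysis, signalling feedback, oestrogen response and reference genes. The rule for named genes was fixed at the same time. It took Cbfa2t3, the 10 largest rises and 10 largest falls past the threshold with the same sign on both arrays and an ordinary gene symbol in the array file, and from each list up to 4 members with the largest change plus any member past the threshold that went against the list's median. No probe below background in both channels was named as changed. A few genes that the rule names are not reported here, and the counts and medians of lists include them. Where a group's channel was saturated or not well above background on both arrays, the comparisons give a gene's fold only as a bound, or no fold where there is none. The normalized ratios of such genes still enter the counts, medians and tests. A bound is the brighter mean over the dimmer mean of normalized log2 channel values, the dimmer raised to the lowest signal well above background, and is open to dye bias.

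The steps were tested on simulated arrays with the real levels, backgrounds and saturation limit, in which 200 of 16583 tested genes were changed. Of 50 genes each changed by 1.2-fold, 1.5-fold, 2-fold and 4-fold, 14%, 82%, 100% and 100% were called in the true direction, with median measured folds of 1.13, 1.44, 1.8 and 3.4. A single unchanged gene (1 of 16383) was called. The simulated noise was drawn from limma's own fitted variance prior, independently for each probe, so a low count of false calls was built in. Levels were the mean of both channels, so the heavier saturation of the red channel was not simulated. Changed genes were not taken from the brightest. When every simulated probe also had a constant dye effect with an SD of 0.15 on the log2 scale, 3404 unchanged genes (20.8%) were called.

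Alternatives covered plain background subtraction, no background correction, normexp with offset 0, the processed signals, the deposited ratios, median centring, the filter on dim probes, the mean of all probes of a gene, removal of the trend in probe base composition, eBayes with an intensity trend or robust, a minimum fold of 1.2 with treat, an adjusted p under 0.1, camera with an estimated correlation, 10000 random lists matched on intensity, and each array alone. Leaving out saturated probes and a limit of 1.5-fold were added after seeing the data. Precision is limited by the number of arrays. Camera with an estimated correlation and fry's directional test rest on 1 residual degree of freedom. Hardly any group of genes could pass under them. Median centring took 0 from all unflagged non-control spots, dim ones included, and leaves any trend of the ratio with brightness in place. The share of spots well above background was 59.4% (Cy3) and 63.1% (Cy5) on array 1 and 57% and 59.7% on array 2. Spike-in controls on the arrays read ratios compressed, with slopes of observed on expected log ratio of 0.805 and 0.812, per the file headers.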

Results

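Transcript levels were measured in G1E-ER-GATA-1 cells, an erythroid line in which β-estradiol activates GATA-1, after 24 h of β-estradiol. Each of 2 arrays set cells given siRNA against ETO2 (gene Cbfa2t3) against cells given control siRNA, and the question was which transcripts depend on ETO2 while GATA-1 drives erythroid maturation. The median spot signal was 82.8 scanner units in the ETO2 siRNA channel and 105 in the control channel on array 1, over local backgrounds of 46 and 47. On array 2 these were 77.5 and 105 over 44 and 46. The red control channel was saturated at 471 and 495 spots, against 39 and 11 in the green ETO2 siRNA channel.

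The targeted gene itself was lower after its siRNA. Cbfa2t3 (NM_009824) had a log2 ratio of -0.42 ± 0.05 (SD, n = 2 arrays), which is 74.6% of the control level (adjusted p = 9.20e-05). With median centring in place of loess the log2 ratio was -0.98. That scaling put the median of all tested genes at -0.31 and of the reference genes at -0.48, so -0.98 is not the size of the knockdown alone. A second Cbfa2t3 probe read -0.23 ± 0.0046, or 85.6% of control. Its relative Cbfa2t2 had a log2 ratio of -0.09 and did not pass the test.

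Several of the largest rises were in genes of red cell maturation. The largest rise was in Slc4a1, the band 3 anion exchanger of the red cell membrane, at a log2 ratio of 2.88 ± 0.07 (SD, n = 2), a 7.36-fold higher signal (adjusted p = 6.17e-13). Slc25a37 (mitoferrin-1, which carries iron into mitochondria for haem synthesis) rose 3.51-fold, with a log2 ratio of 1.81 ± 0.01. Rragd, a Rag GTPase of amino acid signalling, rose 3.46-fold, Tmod1 (tropomodulin of the membrane skeleton) 3.09-fold and Epb42, also of the membrane skeleton, 2.63-fold. Pigq, Aqp8, the embryonic globin Hba-x, Vangl1 and Nupr1 completed the 10 largest rises among genes with an ordinary symbol in the array file, between 2.32-fold and 2.53-fold. Erfe, the erythroblast hormone that acts on hepcidin, and Hemgn, an erythroid nuclear protein, lie outside that choice, were picked after their values were seen and rose 2.41-fold and 2.14-fold.

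The largest fall was in Ptgir, the prostacyclin receptor, which fell 3.67-fold, with a log2 ratio of -1.87 ± 0.01 (SD, n = 2; adjusted p = 8.21e-11). Socs1, a feedback inhibitor of cytokine signalling, fell 3.64-fold (log2 ratio -1.86 ± 0.16) and Hmga1, a chromatin protein, 3.43-fold (log2 ratio -1.78 ± 0.14). Plekhg3 fell 3.2-fold, the inhibitory receptor Pirb 2.92-fold, Alox5ap (the 5-lipoxygenase activating protein) 2.8-fold and Hkdc1 2.78-fold. The integrin Itgal, the receptor Cd200r3 and Hdc, which makes histamine, fell 2.77-fold, 2.62-fold and 2.61-fold. The background correction added an offset to both channels, which draws the measured folds of dim genes toward no change. Ptgir, Hkdc1 and Hba-x were dim, at mean log2 signals of 6.77, 6.51 and 6.62 in their dimmer channel. Their folds are therefore likely too small, and the order of the largest changes may depend on the offset. With offset 0, 46 genes were at least 2-fold higher and 65 lower in both arrays, against 25 and 38.

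**Figure D1:**
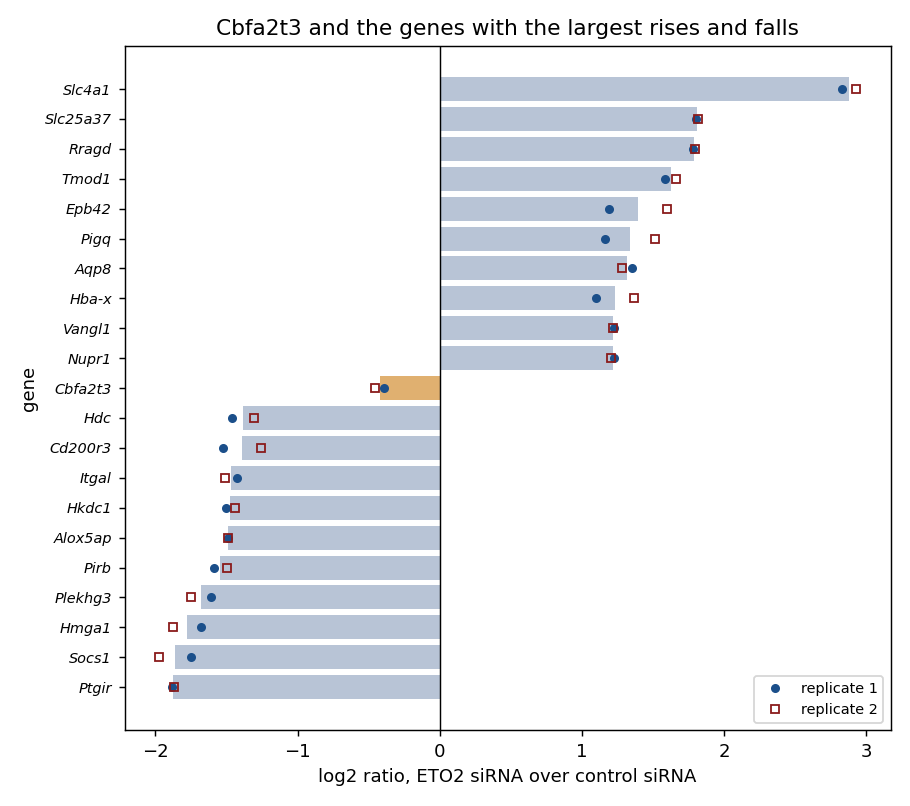
Log2 ratio of ETO2 siRNA over control siRNA (horizontal axis) for Cbfa2t3 and the genes with the 10 largest rises and 10 largest falls (vertical axis). Bars are means of 2 arrays, filled circles are replicate 1 and open squares replicate 2. Slc4a1 stands at 2.88, Ptgir at -1.87 and Cbfa2t3 at -0.42. Both arrays lie on the same side of 0 for every gene drawn, which the rule for choosing the rises and falls required.

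Across all 16581 genes and transcripts, 3050 were higher and 3694 lower in the ETO2 siRNA channel at an adjusted p under 0.05 (limma), against 8029 at an unadjusted p under 0.05. Most of these differences were small: 6167 of the 6744 calls (91.4%) were under 1.5-fold. At least 2-fold in both arrays, 25 genes were higher and 38 lower, against 80 and 85 on the processed signals and 6 and 285 with median centring, and 29 and 64 were higher in array 1 and in array 2 alone. Across genes, which are not independent replicates, the log2 ratios of the arrays correlated with a Pearson r of 0.861 and a Spearman rho of 0.801, and the median SD between arrays was 0.0625. Without a dye swap a constant dye effect of a probe is counted as a change. With median centring in place of loess, the median of all tested genes moved to -0.31 and the calls split into 464 higher and 10809 lower, or 4.12% higher against 45.2% with loess. Median centring takes its 0 from all non-control spots, dim ones included, and leaves in place a trend of the ratio with brightness, which loess removes.

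Erythroid membrane and blood group genes rose as a group. Of 20 measured members, 16 rose, 2 fell and 2 did not pass. Besides Slc4a1, Tmod1 and Epb42, Rhag (Rh-associated glycoprotein) rose by a log2 ratio of 0.76 ± 0.39. Ank1 (ankyrin, -0.24) and Cd24a (-0.20) fell. No member fell on the processed signals or the deposited ratios, where fewer genes fell in all (1267 and 1213, against 3694). The list's median log2 ratio was 0.53 (camera adjusted p = 4.90e-10; adjusted p = 0.766 with an estimated correlation). Tspan33 was the only member among the 16 whose control channel was saturated.

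Haem synthesis genes rose too, with 12 of 16 past the threshold above 0, 1 below and a median log2 ratio of 0.45 (camera adjusted p = 3.66e-07; adjusted p = 0.766 with an estimated correlation). Alas2, the rate-limiting erythroid enzyme of the pathway, rose by 1.04 ± 0.17, Uros by 0.73 ± 0.06 and Urod by 0.49 ± 0.03. Tmem14c, a carrier of haem precursors, fell (-0.18), but read 0.17 on the processed signals and on the deposited ratios, where no haem gene fell. Glrx5 and Alad had a saturated control channel on both arrays, so that no fold is given for them, and Cpox (0.24) on 1 array. With saturated probes left out, an alternative added after seeing the data, 8 of 12 members rose and 1 fell.

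Among globins, 6 of 7 measured genes were above 0 and past the threshold and none fell, with a median log2 ratio of 0.74 (camera adjusted p = 1.80e-05; adjusted p = 0.766 with an estimated correlation). The adult genes Hba-a1 and Hbb-bt were saturated in both channels and Eraf, the stabilising partner of α-globin, in the control channel, so that no fold can be given for these 3. Where both channels are at the scanner's limit, a ratio above 0 comes from the normalization and not from a measured difference. The list's median of 0.74 is itself the normalized ratio of a saturated gene. The unsaturated members that rose were Hba-x (log2 ratio 1.23 ± 0.19), Hbq1a (0.34) and Hbb-y (0.16). With saturated probes left out, 3 of 4 members rose and the list's median was 0.25 (camera adjusted p = 0.0359). Against 10000 random lists matched on intensity, the medians of all 3 erythroid lists lay above at least 99.99% of lists (adjusted p = 0.00153). This test kept saturated probes, so its globin result rests in part on the 3 genes without a measured fold. Under median centring the medians of the membrane, haem and globin lists were -0.02, -0.15 and 0.08, which is 0.29, 0.16 and 0.39 above the median of all genes, and the calls against 0 became 7 higher and 7 lower, 3 and 7, and 3 and 2. fry, which tests each list against 0, called none of the 23 lists as moving one way (lowest adjusted p = 0.101). Its directional test rests on 1 residual degree of freedom, so this failure says little about the lists. Unadjusted fry p-values were 0.0247, 0.0061 and 0.0449 for the globin, haem and membrane lists.

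Erythroid transcription factors did not move as a group. Of 20, 9 rose, 4 fell and 7 did not pass, with a median of 0.06 (camera adjusted p = 0.216). Under median centring 1 rose and 18 fell, but 10809 of all 16581 genes fell there. The list's median was then -0.097 relative to all genes. On the processed signals and on the deposited ratios none fell, but fewer genes fell there in all (1267 and 1213, against 3694). The erythropoietin receptor Epor (0.51), Sox6 (0.50), Tal1 (0.40) and Nfe2 (0.34) rose. Bach1 (-0.31), Zbtb7a (-0.29) and Gata1 (-0.18) fell, and Gfi1b, saturated in the control channel, was at least 1.37-fold lower. G1E lacks GATA-1 of its own, and whether the Gata1 probe reads the introduced GATA-1 fusion is not given in the sources used here. Zfpm1 was saturated in the control channel and is given no fold. In the ETO family and its corepressor partners, 2 of 17 rose and 3 fell (median -0.02, camera adjusted p = 0.742). Irf2bpl (-0.88 ± 0.02), Zbtb33, known as Kaiso (-0.51), and Rcor1 (-0.35) fell, and the deacetylase Hdac2 (0.42) and Zbtb4 (0.19) rose.

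Several progenitor genes that GATA-1 is known to lower fell after ETO2 siRNA. Of 19 measured, 9 fell, 4 rose and 6 did not pass, and the list's median of -0.08 was not past the threshold (camera adjusted p = 0.0801; adjusted p = 0.766 with an estimated correlation). Gata2 fell by 1.07 on the log2 scale (SD 0.02, n = 2), the stem cell factor receptor Kit by 0.98 (SD 0.10), Ccnd2 by 0.80 and Rgs18 by 0.73. Myc (0.30), Lyl1 (0.23), Runx1 (0.23) and Spi1 (0.18) rose, while a second probe of Runx1 read -0.27. The list passed the threshold when all probes of a gene were averaged (adjusted p = 0.00877) and on the processed signals (adjusted p = 0.0344).

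Cytokine feedback and immediate early genes held some of the largest falls: 9 of 19 fell and 3 rose, with a median of -0.15 (camera adjusted p = 0.0801; adjusted p = 0.766 with an estimated correlation). Beside Socs1, Socs2 fell by 1.09 on the log2 scale (SD 0.01), the early growth response gene Egr1 by 0.74 and Cish by 0.63. Smad6 (0.51), Dusp1 (0.32) and Ier3 (0.27) rose.

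Markers of other blood cells moved both ways. In the mast cell, basophil and eosinophil list, 4 of 11 rose and 4 fell (median -0.06, camera adjusted p = 0.742). Hdc (-1.38), the eosinophil granule protein Prg3 (-1.06), the granule proteoglycan Srgn (-0.999) and Prg2 (-0.61) fell. The mast cell proteases Mcpt1 (0.66) and Mcpt4 (0.49) and the receptor Il1rl1 (0.44) rose, and Mcpt2, not well above background in control, was at least 1.38-fold higher. In the granulocyte and macrophage list, 5 of 12 fell and none rose (median -0.12, camera adjusted p = 0.175). These were the Fc receptor Fcgr3 (-0.93 ± 0.20), Prtn3 (-0.33), Tyrobp (-0.28, well above background in the ETO2 siRNA channel on 1 array), Fcer1g (-0.26) and Cebpb (-0.19). Of 16 megakaryocyte and platelet genes, 3 rose and 5 fell (median -0.04, camera adjusted p = 0.8). Gp9 (1.19 ± 0.12), Gp6 (0.68) and Pf4 (0.36) rose, and Nrgn (-1.03 ± 0.07) and the integrin Itgb3 (-0.63) fell.

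Few lymphocyte and tissue markers were measured. Of 10 lymphocyte genes, Vpreb1 rose (0.29) and 2 fell, Cd3e (-0.26) among them (median -0.06, camera adjusted p = 0.781). Of 8 embryonic stem cell genes, Tcl1 (-0.30), Sall4 (-0.28), Utf1 (-0.23) and Dnmt3l (-0.21) fell and none rose (median -0.14, camera adjusted p = 0.175). Of 5 fibroblast and endothelial genes, Eng rose (0.21), and Col1a2, Tek and Postn stood at -0.06, -0.04 and 0.03 without passing (list median 0.01, camera adjusted p = 0.781). Of 5 oestrogen-responsive genes, Ctsd rose (0.47), Xbp1 fell (-0.21), and Tff1 (-0.17) and Nrip1 (0.15) did not pass (median -0.06, mean 0.04, camera adjusted p = 0.8).

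Cell division genes gave a mixed picture. In the S phase and mitosis list, 12 of 30 were above 0 past the threshold and 5 below (median 0.05, camera adjusted p = 0.0801; adjusted p = 0.766 with an estimated correlation). Ube2c (0.65) and Ccne1 (0.52) rose, while Mki67 and Mcm6 had a saturated control and are given no fold. Ccna2 (-0.34), Ccne2 (-0.33), Cdc20 (-0.26), E2f1 (-0.23) and Plk1 (-0.17) fell. On the processed signals and on the deposited ratios 1 member of the list fell and Plk1 read 0.058. Fewer genes fell there in all (1267 and 1213, against 3694). On the processed signals this list passed the threshold (adjusted p = 0.00105), while under median centring 25 members fell, none rose and the median was -0.54, or -0.24 relative to all genes. Of 19 cell cycle inhibitors, apoptosis genes and p53 targets, Gadd45a rose (0.52) and 8 fell, among them the CDK inhibitor Cdkn1b (-0.44), Ddit4 (-0.40) and Bcl2l1 (-0.37), though other probes of Bcl2l1 read 0.10 and 0.27 (median -0.06, camera adjusted p = 0.471).

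Organelle, iron and stress genes split in direction. For autophagy and mitochondrial clearance, 3 of 19 rose and 4 fell (median -0.06, camera adjusted p = 0.8): Gabarap (0.76 ± 0.25), Atg4b (0.57) and Becn1 (0.31) rose, and Bnip3 (-0.46) and Sqstm1 (-0.38) fell. In the iron list, 5 of 15 were above 0 past the threshold and 4 below (median 0.03, camera adjusted p = 0.553). The ferrireductase Steap3 rose (0.72), the ferritin heavy chain Fth1 had a saturated control and no fold, and the transferrin receptor Tfr2 (-0.53), Hmox1 (-0.50), Aco1 (-0.42) and Hpx (-0.20) fell. In the list of unfolded protein, amino acid and heat stress, 7 of 19 were above 0 and 7 below (median 0.03, mean -0.05, camera adjusted p = 0.8). Of those above 0, 3 had a saturated control. With saturated probes left out, 5 of 17 were above 0 and 7 below, and the median turned to -0.13. Txnrd1 (-0.80), Hsph1 (-0.53), Psat1 (-0.39), Nqo1 (-0.30), Xbp1 and Herpud1 (-0.19) fell, and Hspa8 had a saturated control and no fold. Of 16 interferon and double-stranded RNA response genes, Ifi35 (0.25) and Usp18 (0.20) rose and 5 fell, with Ddx58 (-0.46), Oas3 (-0.25) and Stat2 (-0.23) the lowest (median -0.06, camera adjusted p = 0.487).

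In cholesterol synthesis, 5 of 20 rose and 6 fell (median 0.05, camera adjusted p = 0.742). Lss (0.39) and Mvk (0.35) were among those that rose, and the regulator Srebf2 (-0.48), Acat2 (-0.32), Sc5d (-0.24), Hmgcs1 (-0.21), Sqle (-0.21) and Fdps (-0.19) fell. In the glycolysis and hypoxia list, 8 of 22 were above 0 past the threshold and 5 below (median -0.02, mean 0.10, camera adjusted p = 0.337). Of those above 0, Aldoa was saturated in both channels and Ldha, Gpi1, Pgk1 and Tpi1 in the control channel, which leaves Pfkl (0.51), Ankrd37 (0.39) and Eno1 (0.29). The glucose transporter Slc2a3 (-0.78) and hexokinase Hk2 (-0.65) fell.

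Reference genes did not stay at 0. Of 16, 8 were above 0 past the threshold and 5 below (median 0.10, camera adjusted p = 0.254), and 6 of those 8 had a saturated control, among them Eef1a1, Rplp0, Pgk1 and Tubb5, which are given no fold. B2m (-0.46), Ywhaz (-0.24) and Polr2a (-0.19) fell, and Hprt, saturated in control, was at least 1.31-fold lower. With saturated probes left out, the median of this list turned to -0.16. Under median centring it was -0.48, or -0.17 relative to all genes. Adjusted over the list alone, the counts matched those over all genes except for 1 further fall each in erythroid transcription factors (5), mast cell genes (5), stress genes (8) and oestrogen-responsive genes (2), and 1 further rise in cholesterol synthesis (6).

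**Figure D2:**
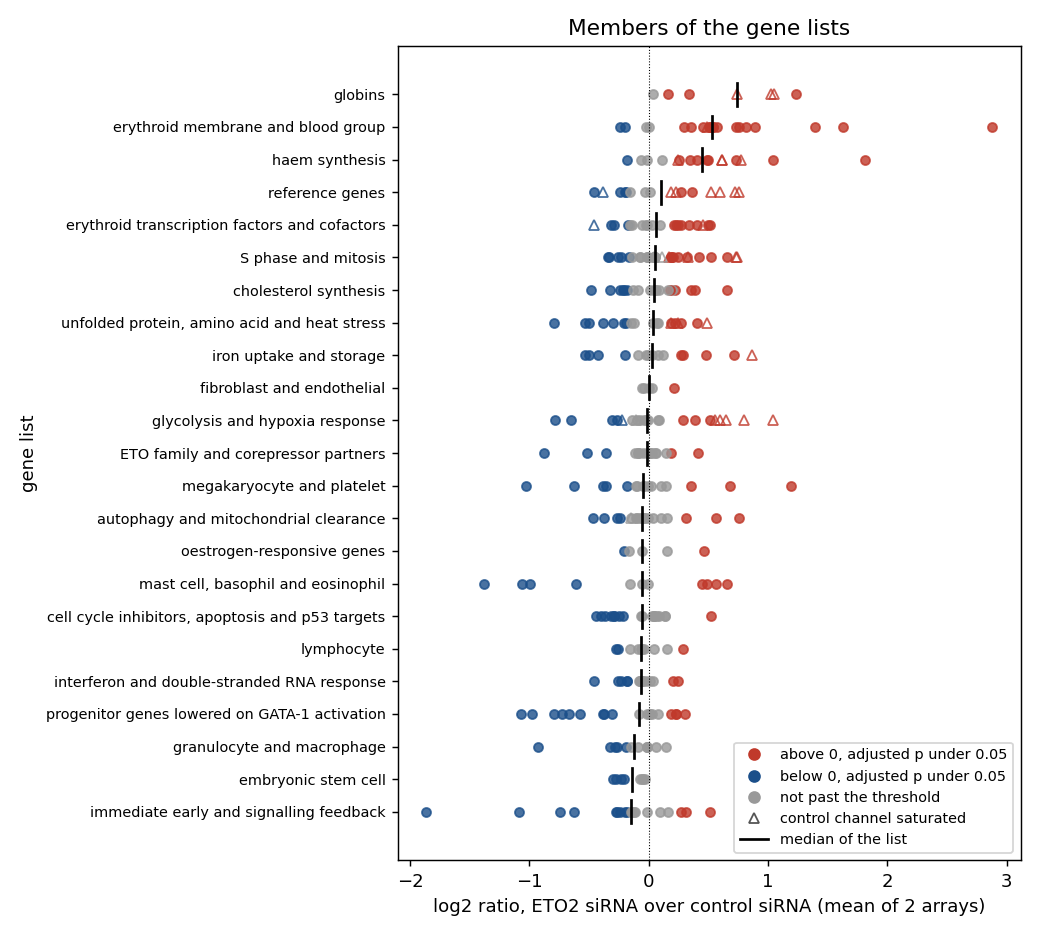
Log2 ratio of ETO2 siRNA over control siRNA, mean of 2 arrays (horizontal axis), for each measured member of the 23 gene lists (vertical axis, ordered by median). Red and blue symbols passed the threshold above and below 0, grey ones did not, open triangles had a control channel saturated on at least 1 array, and black bars are medians, the highest being 0.74 (globins), 0.53 (erythroid membrane) and 0.45 (haem synthesis). With saturated probes left out, these 3 medians were 0.25, 0.53 and 0.38, so that globins were no longer the highest.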

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

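The sign of Cbfa2t3, and the upward calls of the 3 erythroid lists relative to other genes with camera's preset correlation, held under every alternative to the processing that tests them. With an estimated correlation the globin, haem and membrane lists (medians 0.74, 0.45 and 0.53) were no longer past the threshold (adjusted p = 0.766 for each). Cbfa2t3 ranged from -0.98 (median centring, where the median of all genes was -0.31) to -0.32 (mean of all probes). The count of calls moved with the scaling, the source of the signals and the minimum fold. Median centring in place of loess left 464 higher and 10809 lower, the processed signals 1192 and 1267, the deposited ratios 1142 and 1213, and a minimum fold of 1.2 with treat 493 and 574. The counts of at least 2-fold in both arrays, higher and lower, were 47 and 71 with plain background subtraction, 46 and 65 with offset 0, 80 and 85 on processed signals, 79 and 84 on the deposited ratios and 6 and 285 with median centring. At least 1.5-fold in both arrays, a limit added after seeing the data, gave 220 and 205. In a single array, 29 and 64 genes were at least 2-fold higher. The correlation of the arrays was 0.755 on processed signals and on the deposited ratios. The cause was not tested. The progenitor list passed the threshold on processed signals (median -0.15), on the deposited ratios (-0.15), with median centring (-0.58), with no dim filter (-0.050), with the mean of all probes (-0.093) and with the base composition trend removed (-0.078). The S phase list passed on processed signals (0.18), on the deposited ratios (0.18) and with no dim filter (0.050), and the granulocyte list on processed signals and on the deposited ratios (-0.15 in each). Only median centring took past the threshold the lists of the ETO family (-0.55), cell cycle inhibitors (-0.60), stress (-0.47), immediate early genes (-0.39) and, upward relative to all genes, fibroblast and endothelial genes (-0.030).

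In either array alone, list medians ran from 0.092 to 0.11 for erythroid transcription factors, from -0.059 to -0.031 for the ETO family, from -0.16 to -0.076 for progenitor genes, from -0.12 to -0.097 for granulocyte genes, from -0.077 to -0.057 for lymphocyte genes, from -0.077 to 0.025 for fibroblast genes, from 0.066 to 0.085 for S phase, from -0.050 to -0.00054 for autophagy, from -0.10 to 0.043 for stress, from 0.014 to 0.059 for iron, from 0.0092 to 0.030 for cholesterol, from -0.018 to 0.045 for glycolysis, from -0.21 to -0.071 for immediate early genes, from 0.039 to 0.14 for reference genes, from -0.10 to -0.033 for cell cycle inhibitors, from -0.056 to -0.022 for megakaryocyte genes, from -0.085 to -0.032 for oestrogen-responsive genes and from -0.093 to -0.042 for the interferon response. These carry no test. Median centring turned to below 0 Zbtb4 (-0.24), Ccne1 (-0.041), Becn1 (-0.20), Gadd45a (-0.064), Lss (-0.093), Mvk (-0.055), Epor (-0.080), Zfpm1 (-0.21), Gpi1 (-0.020), Pgk1 (-0.064), Tpi1 (-0.11), Pfkl (-0.0024), Ankrd37 (-0.14), Eno1 (-0.24), Dusp1 (-0.22), Ier3 (-0.10), Ifi35 (-0.29), Usp18 (-0.14), Pf4 (-0.19), Ctsd (-0.13), Nrip1 (-0.25), Myc (-0.26), Lyl1 (-0.35), Runx1 (-0.16), Tubb5 (-0.14) and Hspa8 (-0.18), where the median of all genes was -0.31. Of these, Zfpm1, Gpi1, Pgk1, Tpi1, Tubb5 and Hspa8 had a saturated control, so that their values are normalized ratios and no measured fold. Plk1 and Tmem14c turned to 0.058 and 0.17 on processed signals and on the deposited ratios, Bcl2l1 and Runx1 to 0.0018 and -0.021 with the mean of all probes, and Gpi1 to -0.075 with saturated probes left out. Of the other values of named genes under an alternative, 166 were no longer past the threshold and 14 newly past it, in an unchanged direction, and 2032 showed no change of call or, in a single array, of a called sign. Low signal limits the dim genes: 372 tested genes were not well above background in the ETO2 siRNA channel on both arrays, and 24 in the control channel.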

Other observations

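The comparison of gene families, the saturation alternative and the choice of Fc receptors were made after the results were seen. The tests of base composition, second probes, unsaturated ribosomal protein genes and neighbouring genes were fixed before their results were seen.

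Several Fc and paired immunoglobulin-like receptors fell. Of 24 families taken from symbol stems, with saturated probes left out, this was the only family past the threshold: 7 of 11 members fell and 4 did not pass, with a median log2 ratio of -0.26 (camera adjusted p = 0.00114; adjusted p = 0.939 with an estimated correlation). The family joined several stems and took in Cd200r3, a CD200 receptor by its symbol. Pirb (-1.55), Cd200r3 (-1.39), Fcgr3 (-0.93) and Fcgr2b (-0.87) were lowest, while Fcgr4 stood at -0.05 and Fcer1a, the mast cell IgE receptor chain, at -0.0045. Pirb, Cd200r3, Fcgr3 and Fcer1g were already known to have fallen when the family was chosen, so it is not independent evidence. Of 8 annexins, 5 fell and none rose (median -0.21, adjusted p = 0.0861), led by Anxa2 (-0.55) and Anxa5 (-0.46). Of 7 subunits of the CCT chaperonin, 5 rose (median 0.27, with 0.15 on array 1 and 0.38 on array 2; adjusted p = 0.0861), with Cct6a at 0.52, although under median centring their median was -0.07 relative to all genes.

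More than 40% of genes passed the threshold (40.7%), mostly under 1.5-fold, in a design whose dyes were not swapped. Probe base composition explained 1.04% and 2.12% of the variance of the log2 ratios on the arrays, and with its trend removed 7052 genes passed, among them 6452 of the 6744 calls in the same direction, which argues against it as the cause. For 184 called genes of at least 1.5-fold that had a second probe with no shared 20-base stretch, the second probe had the same sign in 87.5% (95% interval 81.8% to 91.9%), which argues against a dye effect of the single probe for these. For 2234 called genes under 1.5-fold it was 65.4% (63.4% to 67.4%), between the limits set in advance, and for 2509 genes not called 55% (53.1% to 57%). A probe-specific dye effect therefore remains open for many of the small calls, and a dye effect that follows the whole transcript was not tested. The arrays shared 1 slide and 1 scan day and may not come from separate cultures. Their raw log2 signals correlated with a Pearson r of 0.9989 (green) and 0.9983 (red), and the median SD between them was 0.0625. The spread behind the calls may therefore leave out differences between cultures, which could also raise their number.

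The brightest genes read well above 0. For 71 ribosomal protein genes with a saturated control channel the median log2 ratio was 0.65, and for 7 genes saturated in both channels on both arrays it was 1.05. With both channels at the scanner's limit, the value for these 7 comes from the normalization and not from a measured difference. The 6 unsaturated ribosomal protein genes had a median of 0.0239, which is consistent with saturation of the red channel, although these genes are few. Under median centring the medians of the saturated and unsaturated sets were -0.01 and -0.45, so that the direction of this family depends on the scaling.

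The rise of erythroid genes was weighed against saturation, base composition and effects of the single probe. With saturated probes left out the median of the members of the globin, haem and membrane lists was 0.475, although that of the globins alone went from 0.74 to 0.25, and with the base composition trend removed it was 0.507, and each argues against that explanation as the whole cause. Second probes of the risen members were above 0 in 100% of 8 genes (95% interval 63.1% to 100%), which argues against effects of the single probe for these 8. The globin, haem and membrane lists held 6, 12 and 16 risen members, so this test did not cover most of them. The rise against 0 depends on the scaling, since median centring put the globin, haem and membrane medians at 0.08, -0.15 and -0.02, where only the position above the median of all genes (-0.31) is left. Transcript-wide dye effects, off-target effects of the siRNA, a difference in how far maturation had gone and an effect of lower ETO2 all stay open and untested, and a dye swap or another siRNA, which would bear on them, was not used here.

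Neighbouring genes may have changed together. Over 11554 pairs of adjacent measured genes whose symbols differ in their stem, with saturated genes left out, the log2 ratios correlated with a Pearson r of 0.0613 (Spearman rho 0.0442), above the highest of 10000 shuffled orders (0.0321; one-sided permutation p = 0.0001, the smallest these shuffles can give). The correlation is weak, is across genes of the same arrays, and shared promoters or overlapping transcripts were not separated. Of 4927 genes with a second probe, none had probes that went in opposite directions by 1.5-fold or more each on both arrays. Few genes changed that much (280 calls above 0 and 297 below at 1.5-fold or more), so this count says little about the agreement of probes. The second probe had the sign of the call in 87.5% of such calls and in 65.4% of smaller ones.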
